A study of Mus musculus with 7 samples.

How the data were processed

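RNA was measured in EPCAM-positive medullary thymic epithelial cells (mTECs) sorted fresh from mouse thymus and lysed in SMART-seq buffer, a chemistry that copies full-length transcripts by template switching and suits small numbers of cells. Of the 7 libraries, 4 came from Cre-negative and 3 from Cre-positive animals, per the labels. Every animal carried Ikzf1 with both alleles floxed, so that Cre can delete part of the gene, and both alleles of Pou2f3 were null. The Cre driver and the floxed exon are not given in the sources used here. Libraries are named here by group and by the number in their label (Cre-negative 46, 48, 75 and 77, and Cre-positive 45, 76 and 80). The labels do not say whether each number is a separate animal, so p-values measure the spread between these samples, which may partly be technical.

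The authors deposited 1 table of 55536 genes. Per the submitters' processing notes, reads were aligned with STAR 2.7.9a, DESeq2 was used downstream, and the genome build was GRCm39. The tool that counted reads per gene and its strand setting are not given in the sources used here. Per the file headers, the table holds for each sample normalized counts, a signal the authors made by dividing gene counts by a size factor per sample and rounded to 1 decimal. It also holds variance-stabilized values on a log2 scale made by the authors, their log2 fold change with its p-value and adjusted p-value, and the GC percent of each gene, which the deposited table takes from an annotation it does not name. Gene coordinates in the table equal those of GENCODE M21, on build GRCm38, for 49909 of the 52403 genes found in both (95.2%), so positions below are given on GRCm38, as the deposited table gives them, although the processing notes name GRCm39. Symbols were missing for 3047 gene IDs and all 3047 were named from a table of gene IDs and symbols.

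Whole reads were recovered from the normalized counts. For each sample, genes read in that sample alone fixed the worth of 1 read to full precision through the unrounded mean over samples, and each value was divided by it. All values came out whole within a rounding tolerance of 0.0501 normalized counts (100% of values in each of the 7 samples), and the means rebuilt from the recovered reads matched the deposited mean for 100% of genes. The recovered totals were 12599078, 9815958, 11755458 and 9816913 reads in Cre-negative 46, 48, 75 and 77, and 11383465, 11394700 and 11623062 reads in Cre-positive 45, 76 and 80. On simulated reads for 55536 genes the same steps recovered 100% of values exactly. Reads carried no molecular identifiers in the sources used here, so counting limits cover counting error only. CPM below are recovered reads scaled to a library's recovered total.

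The test planned before the data were examined was edgeR's quasi-likelihood test for raw counts, with a written fallback for normalized values, and the fallback is the main test because the deposited unit is a normalized signal. Genes with a mean of at least 5 normalized counts over the 7 samples were tested (22878 genes, with 32658 left out) by limma with an intensity trend on log2(normalized count + 1), with genotype as the only term. Fold changes are therefore on the log2(value + 1) scale, as differences between means of logs. The added count shrinks changes of genes near 0 reads, and single libraries near 0 weigh heavily, so a fold change can lie below or above the ratio of the group means. Positive values are higher in Cre-positive samples. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called; every adjusted p below is from limma unless another tool is named. Gene lists were tested with camera on the same values, with a preset inter-gene correlation of 0.01, and with Benjamini-Hochberg adjustment over the 28 lists with at least 3 tested members. The plan named log2 CPM with a prior count of 2 for camera, which fits raw counts; camera was run on the log2(normalized count + 1) values instead. Two-sided exact permutation tests on single library measures double the smaller tail and, with 4 against 3, cannot give a p below 0.0571. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

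The tests were run on simulated reads with the real means, library sizes and dispersions, in which 200 genes were changed. In that simulated comparison of the 2 genotypes, limma tested 22674 genes and called 17 of 100 genes changed by 2-fold and 64 of 100 changed by 4-fold, with 8 false calls and no called gene of the wrong sign. edgeR tested 19785 genes and called 14 and 63, with 5 false calls, and DESeq2 tested 20031 genes and called 22 and 78, with 59 false calls. Camera called 0 of the 28 lists in these simulated data, in which genes vary independently.

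Named genes follow a rule written before the data were examined. It takes Ikzf1, Pou2f3 and Aire whatever their values. It takes the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM and groups that do not overlap, leaving out predicted, non-coding, pseudogene, immunoglobulin and T cell receptor segment, X-inactivation and Y-linked genes. It also takes the 3 tested members of each list with the smallest p; the rule allowed fewer for a list that moves little, and that was not used. The 28 lists, written from general knowledge of thymic epithelium, are Aire-stage mTEC, Aire-dependent tissue antigens, Fezf2-dependent tissue antigens, Ccl21a-type immature mTEC, cell cycle, tuft, neuroendocrine, microfold, keratinocyte, ciliated, muscle, enterocyte and hepatocyte, ionocyte, airway and goblet, pancreatic acinar and parathyroid mimetic cells, the Ikaros family, NF-kB and RANK signalling, interferon response, mTEC chemokines and cytokines, epithelial genes, cortical TEC, thymocyte, myeloid, B cell, fibroblast and endothelial markers, dissociation stress, and mitochondrial transcripts. Where every Cre-positive library was at 0 reads, a fold is a lower bound of the Cre-negative mean against 3 reads over the group.

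Other settings fixed before the data were examined were edgeR with RLE scaling, DESeq2, limma-voom with sample weights, no filter on low genes, a filter of 1 CPM in 3 samples, leaving out each library, a term for the range of the sample number, the summed Y-linked expression as a covariate, a test for changes beyond 1.5-fold, pseudocounts of 0.5 and 5, and for lists an estimated correlation and fry. Added after seeing the data were edgeR with TMM on the recovered reads, TMM and library total scaling under limma, the authors' variance-stabilized values, the samples numbered 75 to 80 alone, and reads thinned to 9815958 per library. Thinned reads were first tested on equal totals without size factors, which amounts to library total scaling, and were then rescaled with median-of-ratios size factors; the second form is the one reported. No per-sample column was left unused for want of a match. Genes listed at 0 in every library, mt-Co2, mt-Co3, mt-Atp6 and Ccl21a among the list members, could not be tested, and Spt1 was not found by that name in the table.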

Results

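Gene expression was measured by SMART-seq RNA sequencing in EPCAM-positive mTECs of 7 mouse thymus samples. Medullary thymic epithelial cells express genes of many peripheral tissues, partly under the regulator Aire, and include mimetic cells, which carry the programmes of peripheral cell types such as keratinocytes or tuft cells. All animals were null for Pou2f3, the transcription factor that tuft cells require, per the labels, and carried floxed Ikzf1, the gene of the transcription factor Ikaros. The 4 Cre-negative samples keep Ikzf1, and the 3 Cre-positive samples are those in which Cre can delete part of it, per the labels. Recovered totals ran from 9815958 to 12599078 reads in the Cre-negative libraries and from 11383465 to 11623062 in the Cre-positive libraries. The comparison asks how mTEC expression differs between the Cre genotypes where Ikzf1 is floxed and Pou2f3 is null, per the labels. Whether Ikaros was lost in Cre-positive samples was not checked.

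The targeted gene was read in every sample. Ikzf1 (ENSMUSG00000018654, chromosome 11, 11685003 to 11772926 on GRCm38) had 1118.7, 1149.5, 1146.8 and 1219.0 normalized counts in Cre-negative 46, 48, 75 and 77, and 1310.3, 1828.6 and 1677.5 in Cre-positive 45, 76 and 80. Its log2 fold change of 0.46 (SE 0.17) did not pass the limma test (adjusted p = 0.0916). The deleted exon is not given and the values are sums over the gene, so the level of Ikzf1 does not check the labels. Pou2f3 had 16.8 ± 10.9 normalized counts in Cre-negative samples (SD, n = 4) and 7.33 ± 9.30 in Cre-positive samples (SD, n = 3), and the difference did not pass (adjusted p = 0.413). A null allele can still be transcribed, so these reads do not check the labels either, and whether tuft cells were absent was not tested.

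In Cre-positive samples, genes of peripheral tissues such as Car1, Retnlb and Lce1j were almost lost, and genes such as Gpx6, Mmp9 and Fxyd2 rose. Of 22878 genes tested, 3150 were called (13.8%), 1066 higher and 2084 lower. With library total scaling 583 were higher and 2629 lower, as the median log2 fold change of all genes moved from -0.10 to -0.29. At an unadjusted p under 0.05 there were 6506 genes. The groups did not overlap for 5788 genes (25.3%, where chance gives 5.71%), among them 3054 of the called genes. Leaving out Cre-negative 46 left 1969 calls, 660 higher and 1309 lower. The count of higher genes was 626, 653 and 590 without Cre-positive 45, 76 and 80. Among called genes that changed more than 4-fold, 194 rose and 1470 fell. Lower genes were 90.4% of the 94 calls with a mean CPM of up to 1, 91.3% of 854 from 1 to 5, 75.4% of 891 from 5 to 20, 48.7% of 873 from 20 to 100, and 27.9% of 438 over 100. The number of genes with at least 10 reads was 20035 ± 453 in Cre-negative libraries (SD, n = 4) and 17453 ± 486 in Cre-positive libraries (SD, n = 3), an exact two-sided permutation p of 0.0571, the smallest that 4 against 3 can give where the smaller tail is doubled. The authors' deposited results call 4257 genes, and 2928 of the 3150 calls (93.0%) are among them, all with the same sign. They hold an adjusted p for 19558 genes, and none for some called here, Car1 and Plpp1 among them.

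**Figure D1:**
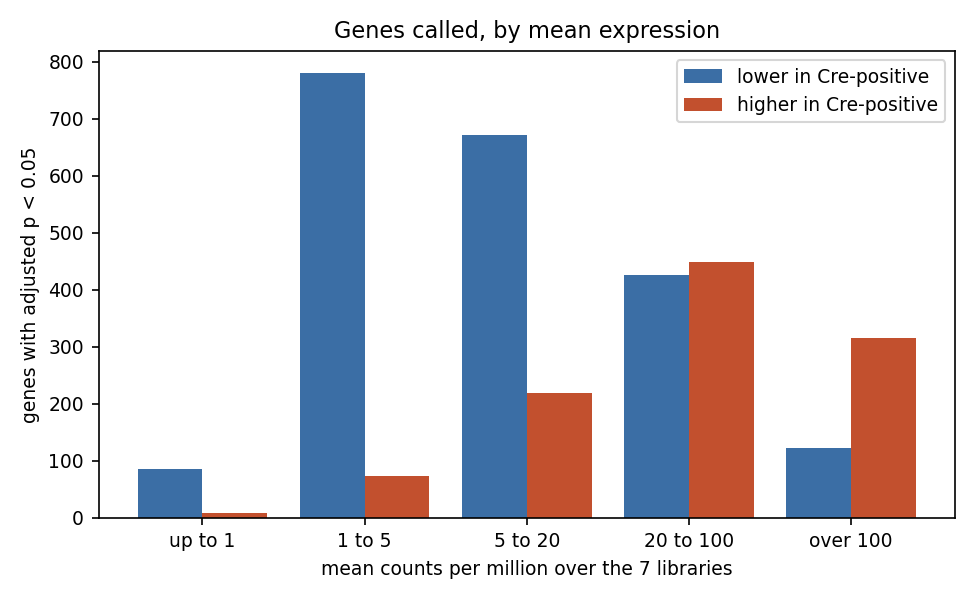
Number of genes called higher and lower in Cre-positive samples (vertical axis) in bins of mean CPM over the 7 libraries (horizontal axis). Lower genes outnumber higher ones up to a mean CPM of 20, with 780 against 74 from 1 to 5, and higher ones lead over 100, with 316 against 122.

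The 10 largest falls were in Car1, Retnlb, Prr9, Lce1j, Stfa1, Rhox12, Crygs, Sprr2f, Defa29 and Lce3b, genes of gut, skin and other peripheral tissues. Car1 (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368) had 681.3, 250.2, 311.7 and 259.5 normalized counts in Cre-negative 46, 48, 75 and 77, and 0, 1.0 and 0 in Cre-positive 45, 76 and 80 (adjusted p = 1.07e-05). Retnlb (ENSMUSG00000022650, chromosome 16, 48816856 to 48818891) fell from 389.5 ± 59.0 (SD, n = 4) to 0, 0 and 9.3 normalized counts in Cre-positive 45, 76 and 80 (adjusted p = 6.86e-05). Lce1j, Stfa1 and Defa29 had no read in any Cre-positive library. Their Cre-negative values were 153 ± 60.5, 176 ± 116 and 134 ± 108 normalized counts (SD, n = 4). Against 3 reads over the group, these means were at least 149-fold, 172-fold and 131-fold higher. The bounds leave out the spread of the Cre-negative libraries, of which Cre-negative 75 had only 34.2 for Stfa1 and 30.6 for Defa29. Prr9 and Sprr2f each had 2.0 normalized counts in Cre-positive 76 and none in the others, against means of 264.0 and 157.5 in Cre-negative samples. Crygs fell from 198.3 ± 113 to 0.667 ± 0.577, Rhox12 from 385.3 ± 149 to 4.87 ± 7.58, and Lce3b from 528.8 ± 345 to 10.4 ± 16.4 normalized counts (SD, n = 4 and 3; adjusted p = 7.84e-05, 1.78e-04 and 6.17e-04). Most Cre-positive reads of Rhox12 and Lce3b were in replicate 45, and the log2 fold change without it was -8.00 for Rhox12 and -8.02 for Lce3b, where all samples gave -6.88 and -6.65. edgeR gave -6.29 for Rhox12 and -5.67 for Lce3b. Lce, Sprr, Stfa, Defa and Rhox genes have close copies between which reads could be split, so values of single members are uncertain.

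The 10 largest rises were in Plpp1, Gpx6, Syp, Igll1, Nlrp3, Umod, Mmp9, Fxyd2, Cyp2a12 and Cib3. Fxyd2 (ENSMUSG00000059412, chromosome 9, 45399669 to 45410278) rose from 2554 ± 520 normalized counts (SD, n = 4) to 25927 ± 3778 (SD, n = 3), a log2 fold change of 3.35 (SE 0.17, adjusted p = 9.12e-07). Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850) rose from 542.2 ± 93.8 to 5520 ± 521 normalized counts (log2 fold change 3.36, adjusted p = 9.12e-07). Gpx6 (ENSMUSG00000004341, chromosome 13, 21312125 to 21319624) rose from 602.5 ± 162 to 8077 ± 1265 (log2 fold change 3.78, adjusted p = 2.32e-06). Igll1, Cib3, Plpp1, Nlrp3 and Umod rose by log2 fold changes of 3.49, 3.10, 3.96, 3.46 and 3.41 (adjusted p = 1.22e-05, 1.28e-05, 6.86e-05, 0.00137 and 0.00784), with 2.80 for Umod without Cre-negative 77. Cyp2a12 rose by 3.12 (adjusted p = 0.00887), and without Cre-positive 76 it was not called (0.0511). Syp rose by 3.62 (adjusted p = 0.0376) and was not called without Cre-negative 46 (0.0774) or without Cre-positive 45, 76 or 80 (0.0863, 0.0996 and 0.0851), or with a pseudocount of 0.5 (0.0562). edgeR gave Syp 2.67 (adjusted p = 0.0520) and DESeq2 2.67 (0.108), neither a call. Its limma log2 fold change was 2.40 without Cre-negative 48, which had no Syp read, and 4.26 without Cre-negative 77. Plpp1, Syp and Umod overlap other genes in position, and the strand setting of the counting is not given.

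Aire and most of the tested Aire-dependent tissue antigens were lower in Cre-positive samples, while several antigens that depend on the regulator Fezf2 were higher. Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610, overlapping Dnmt3l) fell from 4417 ± 767 normalized counts (SD, n = 4) to 2967 ± 308 (SD, n = 3), a log2 fold change of -0.56 (SE 0.17, adjusted p = 0.0395). It was not called without Cre-negative 75 or 77 (adjusted p = 0.0931 and 0.0941) or without Cre-positive 45 or 76 (0.104 and 0.134). The costimulators Cd80 and Cd86 fell, Cd80 from 1170 ± 266 to 316.9 ± 58.0 normalized counts (log2 fold change -1.87, adjusted p = 2.51e-04) and Cd86 by -1.82 (adjusted p = 0.00937). The list of Aire-stage mTEC genes as a whole was not called (3 of 12 lower, camera adjusted p = 0.335). Of 10 tested Aire-dependent antigens 8 were lower, with a median log2 fold change of -3.27, and the list was called with the preset inter-gene correlation (camera adjusted p = 2.26e-07) but not with an estimated one (0.269). The milk casein genes Csn1s1 and Csn1s2a fell by -4.06 and -5.17 and the neuronal gene Pcp4 by -3.48 (adjusted p = 2.80e-04, 3.61e-04 and 0.00102). Csn2, another casein gene of the same list and the more abundant one, named here after its values were seen, was not called (18736 ± 2137 and 15490 ± 6275 normalized counts, log2 fold change -0.35, adjusted p = 0.351). Csn1s2a gave -4.52 without Cre-positive 45, -6.29 without 80 and -4.37 in edgeR. Pcp4 gave -2.75 without 45 and -4.29 without 80, and Csn1s1 gave -3.44 without 76. Of 7 Fezf2-dependent antigens 4 were higher and 1 lower, and the list was not called (camera adjusted p = 0.0742). Crp rose from 239.3 ± 50.4 to 1723 ± 234 normalized counts (log2 fold change 2.86, adjusted p = 1.22e-05), and Calb1 and Col17a1 rose by 2.23 and 1.46 (adjusted p = 0.00391 and 0.00325).

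**Figure D2:**
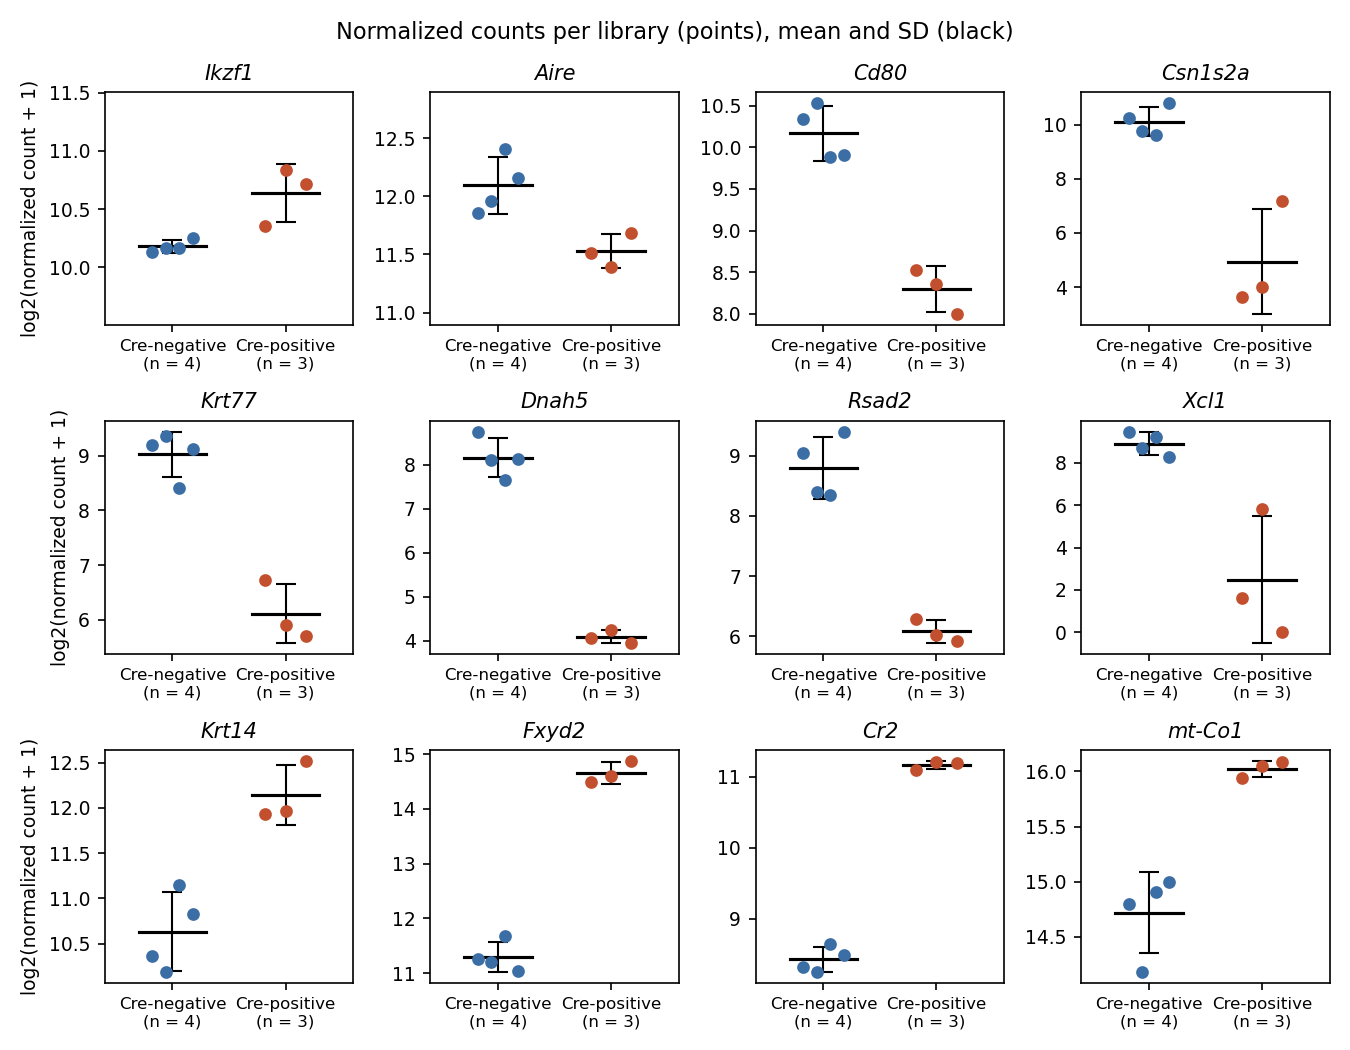
Normalized counts of 12 genes on a log2(value + 1) scale (vertical axes) in the 4 Cre-negative and 3 Cre-positive libraries, as points, with the mean and SD in black. Aire, Cd80, Csn1s2a, Krt77, Dnah5, Rsad2 and Xcl1 lie lower in all 3 Cre-positive libraries than in any Cre-negative library. Ikzf1, Krt14, Fxyd2, Cr2 and mt-Co1 lie higher in all 3, though Ikzf1 did not pass the limma test (adjusted p = 0.0916).

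Among mimetic programmes, many keratinocyte, airway and goblet and pancreatic acinar genes were lower in Cre-positive samples, and ciliated genes moved in both directions. None of these 4 lists was called with an estimated inter-gene correlation. In the keratinocyte list 8 of 14 genes were lower (median log2 fold change -1.46, camera adjusted p = 6.96e-05, or 0.269 with an estimated correlation). Krt77 fell from 535.3 ± 136 to 71.5 ± 28.9 normalized counts (SD, n = 4 and 3; log2 fold change -2.92, adjusted p = 1.64e-04), and Ivl and Grhl3 fell by -4.52 and -1.50 (adjusted p = 0.00601 and 0.00696), Ivl by -5.38 without Cre-positive 76. With limma-voom Ivl was not called (adjusted p = 0.0548). In the pancreatic acinar list 5 of 8 genes were lower (median -2.67, camera adjusted p = 3.66e-04, or 0.133 estimated), among them Prss2, from 406.0 ± 197 to 75.5 ± 32.6 normalized counts (log2 fold change -2.31, adjusted p = 0.00512), Pnliprp1 (-4.49, adjusted p = 0.00215) and Cela1 (-3.76, adjusted p = 0.0150). Cela1 gave -4.85 without Cre-positive 45 and -2.82 without 80, and edgeR gave it -3.09 and did not call it (adjusted p = 0.0648). In the airway and goblet list 4 of 8 genes were lower (median -1.71, camera adjusted p = 0.00746, or 0.269 estimated), with Scgb1a1 from 1049 ± 220 to 244.8 ± 125 (log2 fold change -2.24, adjusted p = 0.00129), Ltf by -2.10 (adjusted p = 0.00937) and Muc2 by -4.10 (adjusted p = 0.0108). Muc2 gave -2.72 without Cre-positive 45, -5.04 without 76 and -3.38 in edgeR. In the ciliated list 3 genes were lower and 1 higher of 12 (median -1.31, camera adjusted p = 0.0419, or 0.526 estimated). Dnah5 fell from 295.2 ± 96.2 to 16.1 ± 1.78 (log2 fold change -4.07, adjusted p = 3.85e-05) and Mcidas by -3.98 (adjusted p = 0.00675; -3.38 without Cre-positive 45 and -4.67 without 76), whereas Ccdc153 rose by 2.75 (adjusted p = 0.00299). The ciliated list was not called without Cre-negative 48 (0.106) or Cre-positive 45 (0.118) or 80 (0.0541).

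The other mimetic lists were not called, although single genes in them moved. Of 16 tuft genes tested only Ltc4s was called (165.5 ± 66.8 against 583.8 ± 164 normalized counts, log2 fold change 1.87, adjusted p = 0.00288; list adjusted p = 0.335). Among 12 neuroendocrine genes 2 were higher and 2 lower (list adjusted p = 0.627), and Scg2 fell by -2.21 (adjusted p = 0.0104). Ret rose by 1.23 (adjusted p = 0.0284) and Neurod1 fell by -3.40 (adjusted p = 0.0341). Ret was not called without Cre-negative 46, 48 or 77 or Cre-positive 76 (0.0510 to 0.126), nor Neurod1 without Cre-negative 46, 48 or 75 or Cre-positive 76 or 80 (0.0711 to 0.101), where its log2 fold change ran from -4.36 without Cre-positive 45 to -2.42 without 80. edgeR and limma-voom did not call Neurod1 (0.0747 and 0.127). Ret was not called with library total scaling (0.0620), and neither gene with the Y-linked covariate (0.0702 for Ret and 0.0785 for Neurod1). Of 11 muscle genes Myog rose by 2.27 (adjusted p = 0.00732) and 3 fell (list adjusted p = 0.449). Actc1 and Chrna1 fell by -2.17 and -1.17 (adjusted p = 0.0254 and 0.0335). Actc1 lost its call without Cre-negative 48, 75 or 77 or Cre-positive 45 or 76 (0.0568 to 0.0817) and gave -2.78 without Cre-positive 80, and Chrna1 lost its call without Cre-negative 46, 48 or 77 or Cre-positive 45 or 76 (0.0777 to 0.104). With the Y-linked covariate neither was called (0.0603 for Actc1 and 0.0788 for Chrna1). Saa3 and Saa1 fell by -1.24 and -1.27 (adjusted p = 0.0101 and 0.0103) in the enterocyte and hepatocyte list (2 of 14 lower, list adjusted p = 0.183), Saa1 with 0.0508 without Cre-positive 76. In the ionocyte list 1 of 9 genes was lower (list adjusted p = 0.235). No gene of 9 was called in the microfold list (list adjusted p = 0.349) and 1 of 3, Pth, in the parathyroid list (list adjusted p = 0.642), whose median was above 0 while camera pointed down. Pth fell from 406.6 ± 240 to 70.0 ± 120 normalized counts (adjusted p = 0.0208), with overlapping groups, and was not called without Cre-negative 46, 48 or 77 or Cre-positive 76 or 80 (0.0575 to 0.0824); its log2 fold change of -5.47 was -7.88, -4.52 and -4.02 without Cre-positive 45, 76 and 80. edgeR gave Pth -2.56 (0.189) and DESeq2 -2.54 (0.401), and limma-voom (0.0830) and the Y-linked covariate (0.0627) did not call it either.

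Several interferon response genes were lower in Cre-positive samples, and NF-kB genes and mTEC cytokines moved in both directions. Of 12 interferon genes 6 were lower and 1 higher (median log2 fold change -0.75, camera adjusted p = 0.00356, or 0.145 with an estimated correlation, which is not a call). Rsad2 fell from 467.7 ± 168 to 66.9 ± 9.36 normalized counts (SD, n = 4 and 3; log2 fold change -2.73, adjusted p = 1.85e-04), Ifit1 by -1.67 (adjusted p = 9.75e-04) and Mx1 by -1.54 (adjusted p = 0.00957). Of 11 NF-kB and RANK genes 3 were lower and 1 higher (camera adjusted p = 0.335). Nfkb1 and Rel fell by -1.02 and -1.20 (adjusted p = 0.00421 and 0.00639), and Tnfaip3 rose by 1.02 (adjusted p = 0.0137; 0.0615 without Cre-positive 45). Of 12 chemokines and cytokines 2 were higher and 3 lower (camera adjusted p = 0.947). Il7 rose from 1452 ± 128 to 3230 ± 465 (log2 fold change 1.15, adjusted p = 6.88e-04) and Ccl19 from 488.1 ± 115 to 1443 ± 393 (log2 fold change 1.56, adjusted p = 0.00125). Xcl1 fell from 506.1 ± 183 to 19.4 ± 31.8 (log2 fold change -6.42, adjusted p = 0.00130), or -8.10 without Cre-positive 76, -5.18 without 80, -4.66 in edgeR and -4.71 in DESeq2.

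Some genes of immature mTECs and all tested mitochondrial mRNAs were higher in Cre-positive samples. Of 7 tested genes of Ccl21a-type immature mTECs 3 were higher and none lower (median log2 fold change 0.57, camera adjusted p = 0.0239, or 0.256 with an estimated correlation, which is not a call). Krt14 rose from 1640 ± 502 to 4594 ± 1115 normalized counts (SD, n = 4 and 3; log2 fold change 1.51, adjusted p = 0.00132). Trp63 and Krt5 rose by 0.74 and 0.59 (adjusted p = 0.0362 and 0.0475). Trp63 was not called without Cre-negative 46 or 77 or any single Cre-positive library (0.0826 to 0.0882), nor Krt5 without any single library except Cre-negative 48 (0.0514 to 0.127) or with a term for the sample number range (0.0523). edgeR (0.0615) and the fit without a filter (0.0604) did not call Krt5, and with library total scaling neither Trp63 (0.118) nor Krt5 (0.197) was called. All 6 tested mitochondrial mRNAs rose (median 1.02, camera adjusted p = 2.44e-08, or 0.133 estimated, which is not a call), mt-Co1, mt-Cytb and mt-Nd5 by 1.30, 1.28 and 1.11 (adjusted p = 8.14e-04, 1.78e-04 and 4.66e-04), and their share of reads was 1.91 ± 0.104% in Cre-negative and 3.47 ± 0.262% in Cre-positive libraries (exact two-sided permutation p = 0.0571). The share of mitochondrial ribosomal RNA was 3.11 ± 0.254% and 3.17 ± 0.0684% (exact permutation p = 0.686). Of 16 cell cycle genes none was called (camera adjusted p = 0.482), and of the Ikaros family 0 of 5 (camera adjusted p = 0.338).

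**Figure D3:**
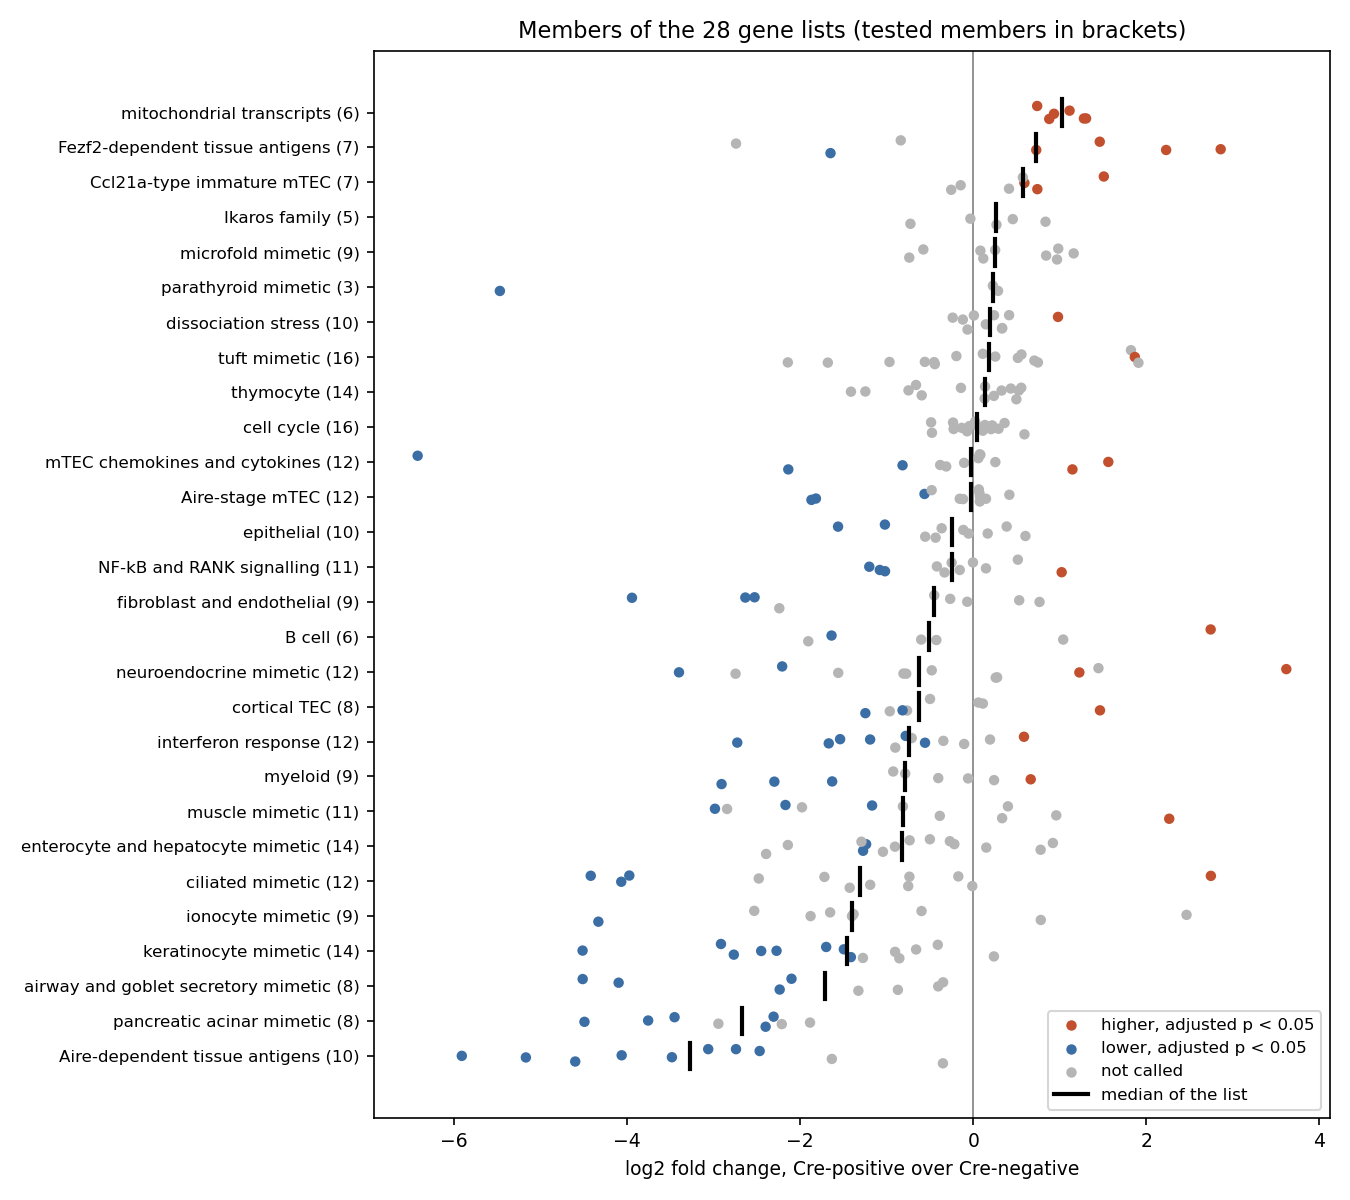
Log2 fold change, Cre-positive over Cre-negative (horizontal axis), of every tested member of the 28 gene lists (vertical axis, with the number tested), as points coloured by call, with the list's median as a black line. The median is lowest in the list of Aire-dependent antigens at -3.27 and highest in mitochondrial transcripts at 1.02.

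Genes of epithelium and of other thymic cells moved in part. Cldn4 and Foxn1 fell by -1.56 and -1.02 (adjusted p = 0.00125 and 0.00236), Foxn1 from 1255 ± 99.5 to 620.2 ± 85.9 normalized counts (SD, n = 4 and 3), and no other of 10 epithelial genes was called (camera adjusted p = 0.298). In the cortical TEC list Ctsl rose by 1.46 (adjusted p = 3.58e-04), and Ccl25 and Dll4 fell by -0.82 and -1.25 (adjusted p = 0.0185 and 0.0478; camera adjusted p = 0.508). Ccl25 was not called without Cre-positive 76 or 80 (0.0833 and 0.0710), nor Dll4 without Cre-negative 46, 48 or 77 or any single Cre-positive library (0.0598 to 0.161) or with a term for the sample number range (0.0589). Dll4 was also not called by edgeR (0.0505) or limma-voom (0.0649), with the Y-linked covariate (0.132), TMM scaling (0.0527) or a pseudocount of 0.5 (0.0503), or without a filter (0.0511). Of 9 myeloid genes 3 were lower and 1 higher (camera adjusted p = 0.158). Adgre1 fell from 296.4 ± 113 to 37.8 ± 16.1 (log2 fold change -2.91, adjusted p = 8.19e-04), Fcer1g by -1.63 (adjusted p = 9.58e-04) and Itgam by -2.30 (adjusted p = 0.00531). Of 6 B cell genes Cr2 rose from 344.7 ± 43.9 to 2303 ± 97.7 (log2 fold change 2.74, adjusted p = 6.27e-06) and Pax5 fell by -1.64 (adjusted p = 0.0220), though not without Cre-negative 48 or 75 or Cre-positive 76 (0.0617 to 0.0702), with limma-voom (0.0606) or with the Y-linked covariate (0.0661). The B cell list was not called (camera adjusted p = 0.449), and its median lay below 0 while camera pointed up. Col3a1 and Col1a2 fell by -3.94 and -2.53 (adjusted p = 0.00350 and 0.00787; -3.08 and -1.94 without Cre-positive 45) in the fibroblast and endothelial list (3 of 9 lower, camera adjusted p = 0.298). Col1a1 fell by -2.63 (adjusted p = 0.0330), with -3.74 without Cre-positive 76 and -1.59 without 80, and was not called without Cre-negative 46, 48 or 77 or Cre-positive 45 or 80 (0.0628 to 0.0972). edgeR gave Col1a1 -1.76 (0.143) and DESeq2 -1.79 (0.200), and limma-voom (0.0607) and the Y-linked covariate (0.0999) did not call it either. None of 14 thymocyte genes was called (camera adjusted p = 0.616). Of 10 dissociation stress genes Atf3 rose by 0.98 (adjusted p = 0.0360; camera adjusted p = 0.232), and not without Cre-negative 46, 75 or 77 or Cre-positive 45 or 80 (0.0571 to 0.125), or with library total scaling (0.0862).

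Of the 28 lists 8 were called, and none held with an estimated inter-gene correlation, where the lowest adjusted p was 0.133. All 8 stayed called with fry (fry adjusted p = 0.00112 to 0.0290). Fry asks whether a list moves at all, rather than whether it moves more than other genes. It also called the Fezf2-dependent (0.0135), myeloid (0.0160), ionocyte (0.0359) and NF-kB and RANK (0.0359) lists. Adjusted over the list alone, counts differed from those over all genes for lower genes in the Fezf2-dependent (2), neuroendocrine (5), keratinocyte (10), ciliated (4), muscle (4), pancreatic (6), interferon (7) and epithelial (3) lists, and for higher genes in the Ccl21a-type (4), B cell (2) and fibroblast and endothelial (1) lists. Cre-negative 48 was the only library with reads of Y-linked genes above 1 CPM, and the samples numbered 45 to 48 and 75 to 80 separated on the second principal component (14.6% of variance), so sex and number range are not the same across samples. Of the called genes named here, the groups overlapped for Pth, Neurod1, Chrna1, Col1a1 and Atf3. Within 45 to 48, with 2 Cre-negative samples and 1 Cre-positive, limma called 0 genes (4362 at an unadjusted p under 0.05), and within 75 to 80, with 2 of each, it called 440.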

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

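The tests of scaling, library depth, other cell types, damaged cells, Y-linked expression against the share of lower genes, and other splits of the samples were chosen after the results were seen, and those of GC content, the nuclear respiratory chain and replicate 80 before the values they measure were seen. Among 142 library measures, list scores and named genes examined in the 4 Cre-negative libraries, 8 had a library far from the other 3, where chance flags about 5% of them. The 8 flags are close to that share, so a single flag may be chance. Xist was at 0.509 CPM in Cre-negative 48, against 169 to 198 in the others of its group, and Y-linked genes at 407 CPM, against 0.0794 to 0.102, so this library differs in sex from the others by these genes. Car1 stood at 681.3 normalized counts in Cre-negative 46 (others 250.2 to 311.7), Gfi1b at 44.5 in Cre-negative 77 (25.6 to 27.0) and Mx1 at 428.0 in Cre-negative 77 (259.1 to 280.2). Myog stood at 61.1 in Cre-negative 48 (30.0 to 35.2), Il7 at 1644 in Cre-negative 75 (1378 to 1404), and Atp6v0d2 at 17.1 in Cre-negative 75 (64.5 to 71.9).

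The number of genes called exceeded that of every other split of the samples. Of the 35 splits into 4 and 3, only 1, the real one, gave as many as 3150 genes, and the highest of the others gave 0. Every other split mixes the genotypes, so a difference between them adds to the spread within groups and keeps calls few. These splits therefore cannot show what chance alone gives, and chance was not excluded for this count. For gene lists, 2 of the 35 splits gave as many as the 8 called, and another split called 10, so chance cannot be excluded for the count of lists.

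Lower genes were 66.2% of the calls, 2084 of 3150, Car1 and Retnlb among them. The tables argue against scaling as the whole cause in the limma and edgeR fits. Their lowest share under TMM, RLE and library total scaling was 63.2%. That minimum leaves out limma-voom, which also scales by TMM and adds sample weights, and which gave 55.2%. The size of the excess thus depends on the method, and limma-voom was not run with another scaling. Thinning could not decide on library depth, since Cre-positive totals, 11383465 to 11623062 reads, lay inside the Cre-negative range of 9815958 to 12599078, and thinning every library to 9815958 reads moved little (66.4% lower). Fewer contaminating cells may contribute and were not excluded. The 38 tested markers of fibroblasts, endothelium, myeloid cells, B cells and thymocytes had a lower quartile of -1.37 and a median of -0.42, against a median log2 fold change of -2.97 for called lower genes, but they moved both ways, with 7 lower and 2 higher, and single ones such as Col3a1 (-3.94) and Adgre1 (-2.91) fell about as much or more. The sort for EPCAM is meant to remove such cells. The share stayed at 66.5% without Cre-negative 48, the only library with Y-linked expression, and was 68.5% with Y-linked expression as a covariate. What stays open is a loss of fibroblasts or macrophages and, untested, whether Cre-positive samples hold fewer mimetic cells or express less per cell.

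Mitochondrial mRNAs rose by a median log2 fold change of 1.02, from 0.74 to 1.30. The tables argue against a trend with the deposited GC percent of the gene. The upper quartile of 740 abundant nuclear genes in the same range of that percent was 0.33, below the lowest mRNA. Whether that percent covers introns is not given, so a trend with the GC of the transcripts was not tested. They argue against scaling, since the median stayed at 0.82 with library total scaling, which moved the median of all genes to -0.29 from -0.10. Damaged or dying cells may contribute and cannot be told apart from the other causes. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 moved by 0.26 (SE 0.14) and 0.23 (SE 0.14), below every mRNA. Their upper limit of 2 standard errors, 0.53, missed the bound set for this test, 0.51, the median of the mRNAs divided by 2, though it lies under the lowest mRNA, 0.74. Nuclear genes of the respiratory chain also rose in part, with 22 of 75 higher and 0 lower by limma. Their median was 0.45 (0.24 with library total scaling, and 0.28 in random lists matched on mean expression). It missed the bound of 0.51, above which it would have counted for a joint rise. The upper quartile, 0.61, lay above 0.51, below which it would have counted against one. Whether these nuclear genes rise with the mitochondrial mRNAs therefore stays open. With library total scaling 60 of the 75, rather than 71, lay above 0.

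Aire-dependent antigens were less reduced in Cre-positive 80. The list kept a median of 24.6% of the Cre-negative mean in replicate 80, against 2.60% in 45 and 6.77% in 76. Cells that kept Ikzf1 intact could leave such a remainder, and if spread over all cell types they would leave it in all lower genes. Of the 1972 genes called lower with a Cre-negative mean of at least 20 normalized counts, 48.3% were below 12.3% of the Cre-negative mean in replicate 80, where a bound of 25% had been set, and the median of these genes was 13.3% in 80, 14.0% in 45 and 14.7% in 76. Lower genes as a set were thus not less reduced in 80. They were called with replicate 80 in the fit, though, which selects against genes with a large remainder there. Intact cells may also not be spread over all cell types. The test therefore cannot decide on such cells, and no other explanation was tested.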

How the results depend on the processing

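TMM in edgeR, TMM and library total scaling, thinning, the authors' variance-stabilized values and the samples 75 to 80 alone were tested after the data were seen. No paired analysis was possible because the groups share no replicate number. The count of calls stayed within 1.5 times of 3150 under no filter (2719), a CPM filter (3198), edgeR with TMM (2747) and RLE (2724), DESeq2 (4390), voom (2631), the number range (3289), pseudocounts 0.5 (3075) and 5 (3163), TMM scaling (3208), variance-stabilized values (3164) and thinning (3105). Leaving out single libraries gave 1969 to 2702 calls, 590 to 1004 higher and 1309 to 1740 lower, from fewer samples. The Y-linked covariate left 2209 calls with 696 higher. Beyond 1.5-fold there were 1163, 196 higher and 967 lower, since the test is stricter. Samples 75 to 80 alone gave 440, 147 higher and 293 lower. Library total scaling gave 583 higher and 2629 lower (81.8% lower, against 1066 and 2084, 66.2%), with the median of all genes moved from -0.10 to -0.29. Voom gave 55.2% lower; the cause was not tested.

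With an estimated correlation 0 lists were called, fewer than 8. Of the 8 called lists, 7 lost their call in 1 to 3 of 23 settings and the ciliated list in 11. Of 20 uncalled lists 8 passed in some setting. Directions of some uncalled lists turned, and the cause was not tested. Camera p with the turned direction was 0.861 for the cell cycle with the Y-linked covariate and 0.134 with samples 75 to 80 alone, where it was 0.783 for neuroendocrine and 0.935 for enterocyte and hepatocyte genes. Leaving out single libraries, some of which turned the direction, gave camera p of 0.0974 to 0.881 for the cell cycle, 0.383 to 0.958 for neuroendocrine, 0.0192 to 0.992 for muscle, 0.564 to 0.994 for chemokine and 0.00937 to 0.943 for thymocyte genes.

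Of 81 called named genes 36 kept their call in all 23 settings, 32 lost it in 1 to 3 and 13 in more, and 0 turned direction. The largest losses were 41 with samples 75 to 80 alone and 25 beyond 1.5-fold. Of 23 uncalled named genes 11 passed in some setting. Uncalled genes that turned sign were Gcm2, Themis, Birc5 and Ccnb1, and the cause was not tested. Gcm2 (0.23) gave -0.21 with edgeR TMM, -0.21 with RLE, -0.21 with DESeq2, -0.031 with voom, -0.11 with the Y-linked covariate, -0.22 with samples 75 to 80 alone, and -0.45 to 0.80 leaving out libraries. Themis (-1.41) gave 0.45 with edgeR TMM, 0.42 with RLE and 0.42 with DESeq2. Birc5 (0.36) gave -0.16 with samples 75 to 80 alone, and Ccnb1 (-0.49) gave -0.98 to 0.0052 leaving out libraries. Between 9815958 and 12599078 reads per library, genes under 1 CPM hold few reads.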

Other observations

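The gene families, the peptide hormone list, the B-lineage genes, the tests of families and the 10 kb distance were chosen after the result was seen, and the test of neighbouring genes before. Families were first formed from name stems with at least 10 genes, then from letters before a digit with at least 8, and only the second form is given.

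Large parts of several families of skin and secretory genes were lower in Cre-positive samples. Of 290 name stems, tested in both directions by Fisher's exact test with Benjamini-Hochberg adjustment over 580 tests, 14 held more lower genes than other protein-coding genes (10.3%) and 4 more higher genes. Lower were 12 of 13 Sprr genes (adjusted p = 9.91e-09), 16 of 25 Klk (3.85e-08), 21 of 49 Krt (7.83e-07), 10 of 12 Spink (1.08e-06), 12 of 20 Lce (7.97e-06), 12 of 27 Defb (4.13e-04) and 7 of 10 Mup genes (7.30e-04), while 3 Krt genes and 1 Defb gene were higher. Higher were 15 of 48 Mrpl genes (1.52e-06) and 10 of 29 Mrps genes (1.06e-04) of mitochondrial ribosomes, with medians of 0.59 and 0.69. With library total scaling 42 of the 48 and 25 of the 29 lay above 0. Genes of a family share reads and neighbourhoods, so they are not independent.

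Many genes of peptide hormones and neuropeptides were lower. Of 63 tested, 38 were lower and 5 higher, with a median log2 fold change of -2.50. The neuroendocrine list fixed before the data were examined was not called (camera adjusted p = 0.627). Of 2 picked after their values and sensitivity were seen, Nts fell from 4151 ± 865 to 291.8 ± 140 normalized counts and Sst from 951.1 ± 238 to 106.9 ± 15.9 (SD, n = 4 and 3; limma adjusted p = 7.52e-06 and 1.30e-05). Pthlh, Hamp, Guca2b, Grp and Adm rose by 1.86, 1.58, 1.36, 1.04 and 0.94 (adjusted p = 1.78e-04, 0.00141, 0.00722, 0.00509 and 0.0125).

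Some genes of B cells, Igkc, Iglc1, Igll1, Cr2 and Fcer2a, chosen after the result was seen, rose by 2.40 to 3.49. Others did not share the rise. Pax5 fell by -1.64 (adjusted p = 0.0220), and Cd79b, at 1.04, was not called (0.0522). Vpreb1, near the floor at means of 10.9 and 11.3 normalized counts, was not called (-0.039, adjusted p = 0.988). The B cell list had a median of -0.51 and was not called (camera adjusted p = 0.449). Immunoglobulin genes have copies between which reads can be split, so values of Igkc, Iglc1 and Igll1 are uncertain. No explanation of the rise was tested.

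Genes called lower tended to be neighbours in the genome. Among 17380 protein-coding genes, 257 neighbouring pairs with different name stems were both lower, against a mean of 169 and a highest of 214 in 10000 permutations within 20 expression bins (p = 0.0001, the smallest they can give). For pairs at least 10 kb apart there were 191 against 93.2. Higher genes also paired (81 against 49.9). Clusters of lower genes beyond families of the same name may exist, although genes with different names can still be related or share an expression domain.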
